A study of Mus musculus with 7 samples.

How the data were processed

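RNA-seq libraries of CD4+CD25+ cells sorted from mouse liver were compared between 3 groups, with 2, 2 and 3 libraries. The authors deposited raw gene counts, 1 column per library, for 53465 Ensembl gene IDs. Reads were aligned with HISAT2 2.1.0 to GRCm38, per the submitters' processing notes. The counting tool, its annotation, its strand setting and the library kit are not given in the sources used here. Groups and replicate numbers came from the labels, and all 7 columns were matched to a sample by title.

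Gene names and coordinates were added from a GENCODE annotation of GRCm38, in which 53360 IDs were found and 105 were not. A gene had a count in at least 1 library for 21106 IDs. Total counts ran from 19731501 to 24398738 per library, so a count of 0 allows up to 0.123 to 0.152 CPM per library (3 counts, covering counting error only). Within groups no 2 libraries agreed within sampling noise (chi-square per degree of freedom from 95.8 to 359). The common dispersion was 0.833, a coefficient of variation of 91.3% between libraries of a group.

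Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, 1 coefficient per group, all 7 libraries), which left 14784 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fitted log2 fold changes use a prior count of 0.125. Where a group had no counts, the pooled CPM of the other group was divided by a floor of 3 counts over the group. Such an "at least" fold covers counting error of the zeros only, not the spread between libraries. CPM values were computed from the deposited counts with TMM-scaled library sizes.

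The gene lists, the rule for named genes and the main tests were fixed before the data were examined. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 42 lists with at least 5 tested members. An estimated correlation and fry were alternatives. A list's mean change is the mean difference of log2 CPM. Adjusted p-values "over the list alone" are edgeR p-values adjusted within 1 list, and not over the 42 lists.

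The rule named Nt5e, 6 Treg genes (Foxp3, Il2ra, Ctla4, Il10, Tgfb1 and Entpd1) and the genes past the threshold. Since none passed, the rule took the 5 with the smallest p in each direction among genes with a mean of at least 5 CPM and groups that do not overlap. Predicted genes, pseudogenes and receptor segments were left out. Other members of lists were named after their values were seen, because they passed adjusted over the list alone, and so were Lyz2, Cd3e and Cd4, without that ground. Fcer1g, H2-Ab1, H2-Aa and Cd74 were named for their abundance, and Cd160 and Eomes because other lists hold them, also after their values were seen. None of these was retested with libraries left out.

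The scripts were tested on simulated data with the dispersions and library sizes of the real libraries and 50 genes changed at each fold size per comparison. For WT_MCD against WT_NCD (13807 genes run), 0% of genes changed 2-fold, 4% changed 4-fold, 48% changed 16-fold and 62% changed 64-fold were recovered. For KO_MCD against WT_MCD (13894 genes run) the shares were 0%, 8%, 42% and 62%, and for KO_MCD against WT_NCD (13877 genes run) 0%, 12%, 32% and 54%, with 4, 2 and 2 false calls. Lists shifted 4-fold were called in 4, 5 and 5 of 5 cases. Genes were simulated independently, so this does not show how far list calls can be trusted where the genes of a list vary together.

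Alternatives were other scalings, low-count filters, DESeq2 1.42.0, limma voom, the replicate number as a block, the 2 groups alone, other thresholds, removal of other cells' genes and each library left out. A macrophage covariate, voom with quality weights, robust edgeR, and a crossed and a same-number block on 2 groups alone, were added after the data were seen.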

Results

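Transcripts were counted in 7 libraries of CD4+CD25+ cells, the surface phenotype of regulatory T cells (Treg), sorted by flow cytometry from mouse liver. WT_NCD stands for wild type mice on a normal control diet (2 libraries). WT_MCD stands for wild type mice fed for 4 weeks a diet lacking methionine and choline, which is widely used to induce fatty liver with inflammation (2 libraries). KO_MCD stands for mice lacking CD73 on the same deficient diet (3 libraries). CD73 is the ectoenzyme that turns extracellular AMP into adenosine, and its gene is Nt5e. Total counts ran from 19731501 to 24398738 per library, and 14784 genes were tested. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Values are CPM (read counts scaled to library size) with SD, and all gene tests are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment.

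The targeted gene was read first. Nt5e (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092, GRCm38) had 242 ± 1.38 CPM in WT_NCD (SD, n = 2), 132 ± 63.0 CPM in WT_MCD (SD, n = 2) and 8.95 ± 4.85 CPM in KO_MCD (SD, n = 3). The 3 knockout libraries had 5.88, 14.5 and 6.43 CPM, below all 4 wild type libraries. In WT_MCD against WT_NCD the Nt5e log2 fold change was -0.87 (SE 0.53, edgeR adjusted p = 0.826). It was -1.48 without WT_MCD replicate 1 and -0.45 without WT_MCD replicate 2. In KO_MCD against WT_MCD the log2 fold change was -3.88 (SE 0.51), with an edgeR adjusted p of 1 over all genes. It passed adjusted over the list alone in the Treg core list (edgeR adjusted p = 0.00205), and DESeq2 called it over all genes (log2 fold change -3.87). The part of the gene that was deleted is not given in the sources used here.

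**Figure D1:**
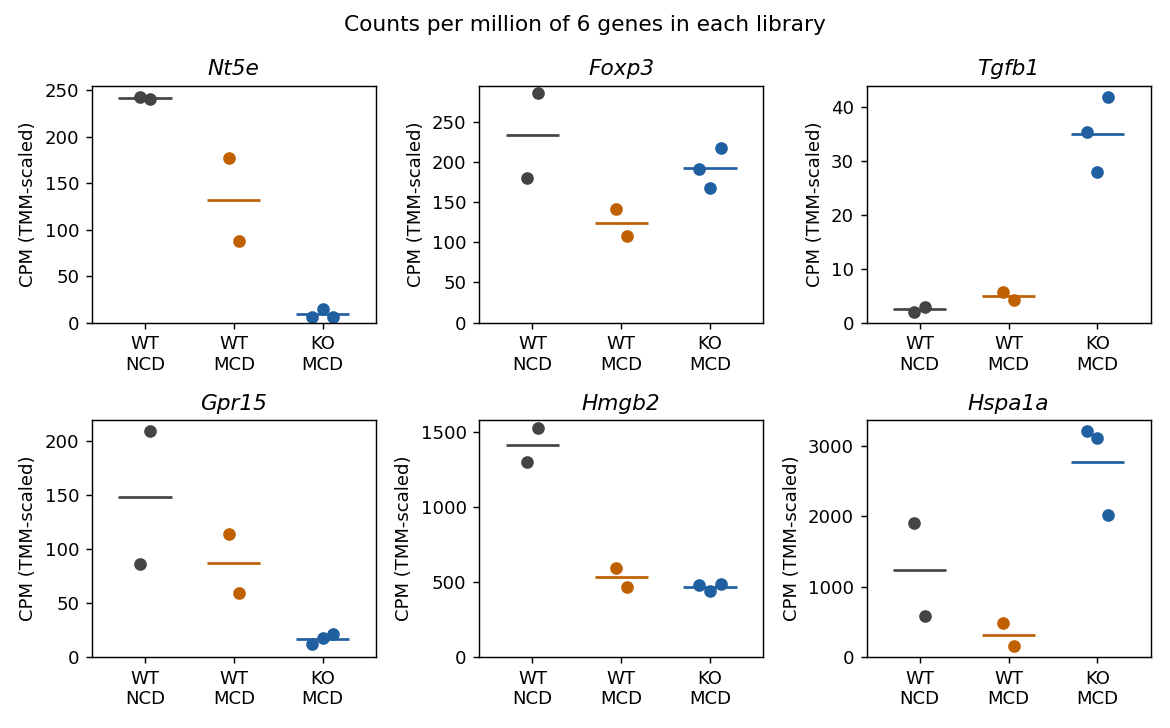
CPM (vertical axes, starting at 0) of Nt5e, Foxp3, Tgfb1, Gpr15, Hmgb2 and Hspa1a in WT_NCD, WT_MCD and KO_MCD; each point is a library and each line a group mean. Nt5e lay at 5.88 to 14.5 CPM in the knockout libraries, and Tgfb1 at 27.9 to 42.0 CPM there.

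WT_MCD against WT_NCD asks how the CD4+CD25+ cells sorted from liver differ on the deficient diet. Every library also held RNA of other cells, so a change need not be one of Treg. The macrophage gene Lyz2 had 845 to 26675 CPM over the libraries, against 93.5 to 303 CPM of Cd3e and 610 to 2137 CPM of Cd4. Genes of natural killer and cytotoxic cells stood higher on the deficient diet, and genes of cell division and of naive T cells stood lower. With an estimated correlation the NK, proliferation and naive T cell lists had adjusted p = 0.193, 0.377 and 0.193. All 21 tested markers of NK, CD8 and gamma delta T cells were higher, with a median log2 fold change of 3.13. Only 9 of these 21 were counted in both WT_NCD libraries, so many of their fitted fold changes rest on counts of 0. Of the proliferation genes 32 of 33 were lower, with a median of -1.25. No single gene passed over all genes tested (edgeR, smallest adjusted p 0.490), while 887 genes had an unadjusted p under 0.05, 586 higher and 301 lower. The 887 were 6.0% of tested genes, where chance gives a share of 0.05. DESeq2 called 307 genes, 249 higher and 58 lower, and limma voom called 0.

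The genes with the smallest p that were higher on the deficient diet were led by receptors of natural killer cells. Ncr1, the activating receptor NKp46, was not counted in WT_NCD and had 27.1 ± 15.0 CPM in WT_MCD (SD, n = 2), at least 379-fold higher against a floor of 3 counts over the group. Klre1, another NK cell receptor, was at least 227-fold higher by the same floor, and Klrd1 (CD94) went from 1.07 ± 0.369 to 36.4 ± 20.7 CPM (log2 fold change 5.08, SE 0.76; 4.34 without WT_MCD replicate 2). The 2 WT_MCD libraries had 16.5 and 37.7 CPM of Ncr1, 9.11 and 23.4 CPM of Klre1 and 21.3 and 6.88 CPM of Ccdc184. The folds against a floor pool both libraries, so the lower library alone would give a smaller fold. Ccdc184 and Nicn1, also not counted in WT_NCD, were at least 208-fold and 138-fold higher. On the lower side, Adk, the kinase that turns adenosine into AMP inside cells, went from 415 ± 99.5 to 128 ± 14.4 CPM (log2 fold change -1.70, SE 0.31). Hmgb2, a chromatin protein abundant in dividing cells, went from 1412 ± 155 to 530 ± 90.5 CPM (log2 fold change -1.41, SE 0.27). Ccr7, the receptor that guides T cells to lymph nodes, went from 1363 ± 260 to 519 ± 57.1 CPM (log2 fold change -1.39, SE 0.27). Patj, a scaffold protein of cell polarity, and the interferon-inducible Ifi209 had log2 fold changes of -2.46 (SE 0.41) and -1.30 (SE 0.27). By the rule all 10 were taken from genes whose libraries did not overlap between the groups. Such genes made up 31.6% of all tested genes, where chance gives 33.3%. None of the 10 passed over all genes (edgeR adjusted p from 0.490 to 0.548).

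Of the 42 lists tested, 9 rose and 8 fell (camera, preset correlation), and none did so with an estimated correlation. The NK, CD8 and gamma delta list rose (camera adjusted p = 5.44e-12; adjusted p = 0.193 with an estimated correlation). Adjusted over the list alone, 4 of its 21 members rose by edgeR, Ncr1, Klre1, Klra9 and Klrb1c, against 0 over all genes. The Th1 and cytotoxic list rose as well (camera adjusted p = 0.000422; adjusted p = 0.193 with an estimated correlation), with 16 of 24 members higher. Fasl, the ligand that triggers apoptosis through Fas, went from 13.3 ± 3.38 to 61.5 ± 0.430 CPM there, and Fasl, Klrd1, Klrk1, Nkg7 and Ly6c2 rose adjusted over the list alone. Dendritic cell markers rose (camera adjusted p = 4.39e-10; adjusted p = 0.377 with an estimated correlation), and 8 of 20 passed adjusted over the list alone, among them Irf8 (log2 fold change 3.07, SE 0.74) and Siglech (2.84, SE 0.71). Of the Th1 and cytotoxic members, Klrd1 also stood in the dendritic list, Ly6c2 in the monocyte and neutrophil list and Fasl in the apoptosis list. Klra9 belongs to a family of near-identical genes, and Irf8 and Klrb1c overlap other genes of the annotation. The counts of Klra9, Irf8 and Klrb1c are thus uncertain where the counting did not separate such reads.

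Proliferation genes fell (camera adjusted p = 1.87e-12; adjusted p = 0.377 with an estimated correlation). Hmgb2, Top2a, Nusap1, Bub1, Aurka and Kif20a, which act in chromatin, chromosome condensation or mitosis, fell adjusted over the list alone. Top2a had 346 ± 149 CPM in WT_NCD and 83.6 ± 9.72 CPM in WT_MCD. The naive and central T cell list fell, with 15 of 16 members lower (camera adjusted p = 9.41e-07; adjusted p = 0.193 with an estimated correlation). Ccr7, Lef1, Dgka, Klf2, S1pr1 and Foxp1 fell adjusted over the list alone. Heat shock genes (14 of 15 lower; camera adjusted p = 0.000661), type I interferon genes (21 of 29; 0.000882) and interferon gamma and antigen presentation genes (16 of 20; 0.00534) also fell. With an estimated correlation their adjusted p was 0.627, 0.608 and 0.608. The heat shock call ended without WT_NCD replicate 1 (mean log2 change -0.37) and WT_MCD replicate 2 (-0.33), the type I interferon call without WT_MCD replicate 1 (0.0054), and the interferon gamma call without WT_NCD replicate 2 (-0.29) and WT_MCD replicate 2 (-0.35). Adk, Patj, Ifi209, Lef1, Foxp1, Dgka, Nusap1, Kif20a and Top2a overlap other annotated genes, so their counts are uncertain too.

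The Treg core list fell, with 16 of 23 members lower and a median log2 fold change of -0.21 (camera adjusted p = 0.0130; adjusted p = 0.627 with an estimated correlation), and 0 members passed adjusted over the list alone. Its call ended without WT_NCD replicate 1 (mean log2 change -0.49), WT_NCD replicate 2 (-0.58) and WT_MCD replicate 2 (-0.12). Foxp3, the lineage factor of Treg, had 234 ± 74.7 CPM in WT_NCD and 124 ± 23.7 CPM in WT_MCD (log2 fold change -0.91, SE 0.34, edgeR adjusted p = 0.803; -0.53 without WT_NCD replicate 2), and it overlaps 4 other annotated genes, among them Ccdc22. Il2ra (CD25), Ctla4, Il10 and Entpd1 (CD39) had log2 fold changes of 0.09 (SE 0.62), -0.66 (SE 0.46), -0.53 (SE 0.71) and -0.10 (SE 0.39). Ctla4 had -1.35 without WT_MCD replicate 1, -0.20 without WT_MCD replicate 2, -0.14 without WT_NCD replicate 1 and -1.03 without WT_NCD replicate 2. Il10 had -1.99 without WT_MCD replicate 1 and -1.07 without WT_NCD replicate 2, and Il2ra had 0.77 without WT_MCD replicate 2 and 0.63 without WT_NCD replicate 2. The signs of Il2ra, Il10 and Entpd1 turned with a library left out (without WT_NCD replicate 1 to -0.30, 0.37 and 0.23; without WT_MCD replicate 1 to -1.28 for Il2ra and 0.26 for Entpd1; without WT_MCD replicate 2 to 0.18 for Il10).

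Markers of other liver cells moved with the diet too. Monocyte and neutrophil (21 of 21 higher), B and plasma cell (17 of 20), Kupffer cell (19 of 23), Th17 (13 of 17), oxidative stress (21 of 23) and cholangiocyte (5 of 5) lists rose, and hepatocyte (15 of 24 lower) and pan T cell (17 of 18 lower) lists fell. Their camera adjusted p ran from 5.19e-05 (pan T cell) to 0.0427 (Kupffer cell), and with an estimated correlation it was 0.377 for cholangiocytes, 0.786 for Kupffer cells, 0.635 for monocytes and 0.627 for the other 5. Lyz2, a lysozyme of macrophages, had 7757 and 845 CPM in WT_NCD, 1837 and 26675 CPM in WT_MCD, and 11324, 8374 and 6151 CPM in KO_MCD. Without WT_NCD replicate 2 the number of lists called was 9 in place of 17, and the Kupffer, monocyte, B cell, pan T cell, oxidative stress and Th17 lists, with mean log2 changes of -0.33, 0.27, 1.42, -0.37, 0.91 and 0.77, were among those not called. Without WT_MCD replicate 2 the Kupffer, monocyte, B cell, pan T cell and oxidative stress lists had -0.20, -0.15, 1.14, -0.18 and 0.17 and were not called. The hepatocyte call ended without WT_NCD replicate 1 (-0.11) and WT_MCD replicate 1 (0.85), the Th17 call without WT_MCD replicate 1 (0.84), and the Kupffer call without any 1 of the KO_MCD libraries (1.29 in each case), which share the estimate of spread. The other 25 lists were not called (camera adjusted p 0.0594 to 0.957).

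**Figure D2:**
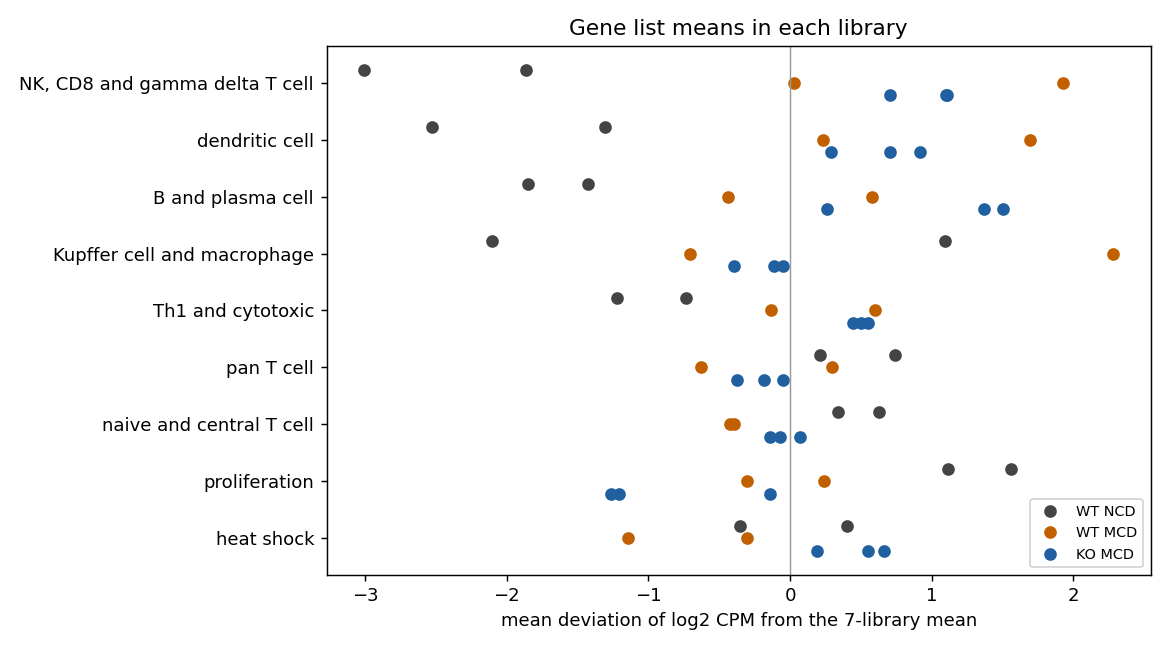
Mean deviation of log2 CPM from the 7-library mean (horizontal axis) for 9 gene lists (vertical axis); each point is a library of WT_NCD, WT_MCD or KO_MCD. NK markers lay at -1.87 and -3.01 in WT_NCD and at 0.03 or above in the other 5 libraries, and WT_MCD replicate 2 had the highest Kupffer cell mean, 2.28.

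KO_MCD against WT_MCD asks what loss of CD73 changes on the deficient diet. Tgfb1 and heat shock genes stood higher in the knockout, and Gpr15 and proliferation genes stood lower. Neither list was called with an estimated correlation (adjusted p = 0.689 for both). The heat shock call ended without WT_MCD replicate 2 (mean log2 change 0.77). In the proliferation list KO_MCD replicate 3 lay between the WT_MCD libraries. Tgfb1 (ENSMUSG00000002603, chromosome 7, 25687002 to 25705077), a suppressive cytokine of Treg, had 4.96 ± 1.0 CPM in WT_MCD (SD, n = 2) and 35.1 ± 7.03 CPM in KO_MCD (SD, n = 3). Gpr15, a homing receptor for the large intestine, had 86.9 ± 38.6 and 17.2 ± 4.50 CPM. No gene passed over all genes tested (edgeR, smallest adjusted p 1), and 480 had an unadjusted p under 0.05, 178 higher and 302 lower. The 480 were 3.25% of tested genes, below the share of 0.05 that chance gives. DESeq2 called 42 genes, 25 higher and 17 lower, and limma voom called 0.

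Tgfb1 had a log2 fold change of 2.82 (SE 0.53). Adjusted over the list alone it rose in the Treg suppressive list (edgeR adjusted p = 0.00954), which also holds Nt5e. In the TGF beta and SMAD list its edgeR adjusted p over the list alone was 0.0210. Hspa1a, an inducible HSP70 chaperone, had 320 ± 230 CPM in WT_MCD and 2776 ± 664 CPM in KO_MCD (log2 fold change 3.12, SE 0.70; 4.18 without WT_MCD replicate 1 and 2.53 without WT_MCD replicate 2). The log2 fold changes of Patj, the tRNA methyltransferase gene Trmt13 and Fam208b were 1.72 (SE 0.38), 2.31 (SE 0.54) and 1.88 (SE 0.45). On the lower side, Eme1, a subunit of a DNA repair endonuclease, was not counted in the 3 knockout libraries and was at least 126-fold lower against a floor of 3 counts over the group. Plekhb2 had 249 ± 0.816 and 105 ± 19.3 CPM (log2 fold change -1.24, SE 0.26). The log2 fold changes of Gpr15 and the cytochrome gene Cyp2s1 were -2.34 (SE 0.49) and -2.59 (SE 0.58). Cyp2s1 (chromosome 7, 25802475 to 25816913) lies close to Tgfb1, which changed the other way. Gpr15 fell in the homing list adjusted over the list alone (edgeR adjusted p = 0.0485). In this comparison 18.0% of tested genes had groups that did not overlap, where chance gives 20%. Hspa1a has a near-identical copy, Hspa1b, Patj overlaps a pseudogene on its own strand, and Hspa1a, Eme1, Trmt13, Fam208b, Gpr15 and Cyp2s1 overlap genes on the other strand, so their counts are uncertain where the counting did not separate such reads.

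Foxp3 had 193 ± 25.2 CPM in KO_MCD against 124 ± 23.7 CPM in WT_MCD (log2 fold change 0.63, SE 0.31). Il2ra, Ctla4, Il10 and Entpd1 had log2 fold changes of 0.41 (SE 0.57), -0.21 (SE 0.42), 0.60 (SE 0.65) and -0.24 (SE 0.35). Without WT_MCD replicate 2 Il2ra, Il10 and Entpd1 turned to -0.27, -0.10 and 0.28, and without WT_MCD replicate 1 Ctla4 turned to 0.50, while Il2ra and Il10 had 1.80 and 2.08. The Treg core list was not called (camera adjusted p = 0.709).

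In this comparison 3 lists rose and 5 fell of the 42 tested (camera), and none with an estimated correlation. Heat shock genes rose, with 14 of 15 members higher (camera adjusted p = 1.34e-06; adjusted p = 0.689 with an estimated correlation). Hspa1a, Hspa1b and Dnajb1 rose adjusted over the list alone, and Dnajb1, a cochaperone of HSP70, had 371 ± 222 and 2146 ± 940 CPM. The T cell receptor and immediate early list rose, with 21 of 27 higher (camera adjusted p = 0.00730; adjusted p = 0.857 with an estimated correlation), and so did B and plasma cell markers, with 17 of 20 higher (camera adjusted p = 2.08e-05; adjusted p = 0.689 with an estimated correlation). Proliferation genes fell, with 32 of 33 lower and a median log2 fold change of -0.76 (camera adjusted p = 2.57e-05; adjusted p = 0.689 with an estimated correlation), and 0 members passed adjusted over the list alone. Hepatocyte (22 of 24 lower; median -3.82, or -3.16 with genes not counted in 1 group at their bound), erythroid and platelet (8 of 8), Kupffer cell (23 of 23) and cholangiocyte (5 of 5) markers fell as well. Their camera adjusted p was 2.08e-05, 0.00408, 0.0437 and 0.0446, and 0.689, 0.689, 0.857 and 0.689 with an estimated correlation. The list means of the 2 WT_MCD libraries lay at -1.10 and 1.99 for hepatocytes and at -0.71 and 2.28 for Kupffer cells. For proliferation they lay at -0.30 and 0.24, with KO_MCD replicate 3 between them (-0.14) and KO_MCD replicates 1 and 2 below both. For B and plasma cells they lay at -0.44 and 0.58, with KO_MCD replicate 3 between them (0.26) and replicates 1 and 2 above both. The groups thus overlapped in both lists, and the differences rest mainly on KO_MCD replicates 1 and 2. Without WT_MCD replicate 2 only the proliferation and B cell calls of these 8 held, and the heat shock, immediate early, hepatocyte, erythroid, cholangiocyte and Kupffer lists had mean log2 changes of 0.77, 0.56, -0.20, -0.47, -1.81 and 0.52. The immediate early call also ended without KO_MCD replicate 1 (0.41) and replicate 2 (0.44), the cholangiocyte call without KO_MCD replicate 1 (-2.29) and replicate 3 (-1.95), and the Kupffer call without KO_MCD replicate 1 (-1.04), replicate 2 (-0.86) and replicate 3 (-1.01). Without WT_MCD replicate 1 the number of lists called was 23, and without KO_MCD replicate 1 it was 5. The other 34 lists were not called (camera adjusted p 0.0699 to 0.999).

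KO_MCD against WT_NCD differs in both diet and genotype, and no knockout group on the control diet was analysed here, so the interaction was not tested. Division genes stood lower and NK, B cell and dendritic markers stood higher in the knockout on the deficient diet. With an estimated correlation the proliferation list had adjusted p = 0.369, the NK list 0.247 and the B cell and dendritic lists 0.443. All 33 proliferation genes were lower, and 18 fell adjusted over the list alone. Zbtb32, a transcriptional repressor of activated lymphocytes, had 104 ± 15.4 CPM in WT_NCD and 11.9 ± 3.35 CPM in KO_MCD (log2 fold change -3.13, SE 0.37). Ncapd2, a condensin subunit, and Top2a had log2 fold changes of -2.50 (SE 0.36) and -2.56 (SE 0.38), Hmgb2 had -1.60 (SE 0.24), and Nt5e had -4.76 (SE 0.52). On the higher side, Ly6d, a surface protein of early B cells, had 4.29 ± 1.09 and 55.8 ± 6.08 CPM (log2 fold change 3.70, SE 0.46), and Fasl had 13.3 ± 3.38 and 99.8 ± 27.2 CPM (2.90, SE 0.40). Ccdc184, Klre1 and Ncr1 were at least 291-fold, 174-fold and 80.9-fold higher. No gene passed over all genes tested (edgeR, smallest adjusted p 0.203), and 1326 had an unadjusted p under 0.05, 698 higher and 628 lower. The 1326 were 8.97% of tested genes, where chance gives a share of 0.05. DESeq2 called 552 and limma voom 0. Here 26.1% of tested genes had groups that did not overlap, where chance gives 20%.

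By camera 9 lists rose and 7 fell, and none with an estimated correlation (smallest adjusted p = 0.247). Their camera adjusted p ran from 6.01e-20 (proliferation) to 0.0385 (IL2 and STAT5). The lists that rose were NK, CD8 and gamma delta (21 of 21 members higher), B and plasma cell (17 of 20), dendritic cell (17 of 20), monocyte (16 of 21), Th1 and cytotoxic (16 of 24), immediate early (24 of 27), TNF and NF-kB (21 of 26), IL2 and STAT5 (16 of 19) and proinflammatory cytokines (14 of 23). With an estimated correlation their adjusted p ran from 0.247 (NK) to 0.841 (monocyte). The lists that fell were proliferation, hepatocyte, pan T cell, naive and central T cell, interferon gamma, type I interferon, and chemokine receptors and homing. With an estimated correlation their adjusted p ran from 0.369 (proliferation) to 0.667 (pan T cell). Ighm, of the B and plasma cell list, fell adjusted over the list alone (log2 fold change -1.01, SE 0.32), while 11 of its members rose, among them Cd79a (3.84, SE 0.63). These lists were not retested with libraries left out. The other 26 lists were not called (camera adjusted p 0.0802 to 0.981).

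The diet and genotype comparisons share the WT_MCD libraries with opposite sign, so chance alone ties them together. Over 14784 genes their log2 fold changes had a correlation of -0.34 and a covariance of -1.50. With 50 simulated sets of unchanged groups the mean correlation was -0.55 and the mean covariance -2.08. The covariance exceeded the simulated mean by 0.58 (simulated range -2.18 to -1.97), by 0.23 over the 9708 genes of mean 5 CPM or more and by 0.31 with a prior count of 2. No gene was called in both comparisons, and the 2 shared libraries were not split, since each comparison would keep 1. The simulated sets share these libraries too, so the excess is over what sharing gives at the simulated spread. Genes were simulated independently, so the simulated range may be too narrow for genes that shift together. The cause of the excess was not tested.

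Knockout strains can carry donor alleles around the targeted gene. No gene was called in KO_MCD against WT_MCD, so genes were counted at an unadjusted p under 0.05, a threshold chosen after the data were seen. The counts were 3 of 81 tested genes within 10 Mb of Nt5e and 476 of the other 14702 (Fisher's exact test, two-sided, p = 0.747). Strain differences at other loci were not tested, among them the locus of Tgfb1 and Cyp2s1 on chromosome 7.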

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

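The macrophage covariate, quality weights, robust fit, the blocks on 2 groups alone and the unadjusted counts near Nt5e were chosen after seeing the data; the cause of each difference below was not tested. The count of 0 genes held in all 3 comparisons under RLE and upper quartile scaling, the stricter filter, limma voom, the replicate block and each left-out library (0 to 0). Without the low-count filter edgeR called 54 genes for WT_MCD against WT_NCD, 1 for KO_MCD against WT_MCD (Nt5e, log2 fold change -3.88) and 140 for KO_MCD against WT_NCD. DESeq2 called 307, 42 (with Nt5e at -3.87) and 552. At an unadjusted p of 0.05 with a 2-fold change the counts were 784, 373 and 1103, with no correction for the number of genes tested. Nt5e ranged from -4.42 to -3.25 over the left-out libraries. List counts of 17 and 8 became 0 and 0 with an estimated correlation and 4 and 0 with fry, and ranged from 9 to 21 and from 5 to 23 over the left-out libraries; where 1 library of a group remained, it was assumed to vary like the other groups. Of the 4 fry lists only 3 were among the 17, namely NK, Th1 and cytotoxic, and naive T cell, and the other was methionine and one-carbon metabolism. The proliferation and dendritic calls were thus lost with fry. With the macrophage covariate 12 and 7 lists were called, ending the Treg core, interferon gamma, oxidative stress, monocyte and Kupffer calls for WT_MCD against WT_NCD and the cholangiocyte and Kupffer calls for KO_MCD against WT_MCD. With the 2 groups alone, 15 lists were called for WT_MCD against WT_NCD, without Th17 and Kupffer. Without the low-count filter the counts were 15 and 7, ending the Kupffer call in both and the hepatocyte call in the first. With the replicate block 16 and 9 lists were called, the Kupffer list in neither, and same-numbered libraries did not deviate together (correlations of -0.10 to 0.03). Crossing the numbers of WT_NCD and WT_MCD called 0 genes and 17 lists. Near Nt5e an unadjusted p gave 3, 1 and 10 genes within 10, 5 and 20 Mb. For WT_MCD against WT_NCD, Il2ra turned to -0.17 (limma voom), -0.18 (quality weights), -0.0029 (replicate block), -0.18 (both blocks on 2 groups), -0.30 without WT_NCD replicate 1 and -1.28 without WT_MCD replicate 1 (range -1.28 to 0.77). Il10 ranged from -1.99 to 0.37 over the left-out libraries (0.18 without WT_MCD replicate 2) and Entpd1 from -0.61 to 0.26 (0.23 without WT_NCD replicate 1). The Kupffer list ranged from -0.33 (without WT_NCD replicate 2; -0.20 without WT_MCD replicate 2) to 2.89, the monocyte list from -0.15 (without WT_MCD replicate 2) to 3.76, the type I interferon list from -0.97 to 0.0054 (without WT_MCD replicate 1) and the hepatocyte list from -2.61 to 0.85 (without WT_MCD replicate 1). For KO_MCD against WT_MCD, Entpd1 turned to 0.058 with the macrophage covariate and ranged from -0.58 to 0.28, Il2ra from -0.27 to 1.80, Il10 from -0.10 to 2.08 and the Kupffer list from -2.43 to 0.52, each with its sign turned without WT_MCD replicate 2, and Ctla4 from -0.66 to 0.50 (turned without WT_MCD replicate 1). Of 813 alternative values of named genes, 753 kept their direction and side of the threshold, 44 newly passed it and 16 turned. Since no named gene passed at first, a gene that again did not pass and kept its sign counted as kept, so this share does not measure robustness. Of 384 alternative values of called lists, 283 kept both, 95 lost the call and 6 turned. Depth limits only the lowest genes, since a count of 0 allows up to 0.152 CPM.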

Other observations

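The tests of explanations for the 3 patterns below were all chosen after the values had been seen. Adora2b, the low-affinity adenosine receptor, was not counted in WT_NCD and had 3.44 and 25.1 CPM in WT_MCD. With both WT_MCD libraries pooled it was at least 195-fold higher against a floor of 3 counts over the group, and the lower library alone would give less. With Adk it was 1 of 2 genes of the adenosine list that passed in WT_MCD against WT_NCD adjusted over the list alone (edgeR adjusted p = 0.0204 and 0.0202). The list itself was not called (camera adjusted p = 0.726). The list of methionine and one-carbon metabolism, which uses nutrients that the diet lacks, was not called by camera (adjusted p = 0.150), while fry gave an adjusted p of 0.0425, with 15 of 25 members lower and a median log2 fold change of -0.03. Tgfb1, at 2.02 to 5.67 CPM in the 4 wild type libraries, overlaps no other gene in the annotation.

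NK and dendritic markers stood higher in both groups on the deficient diet than in WT_NCD, in cells sorted as CD4+CD25+, a gate that would remove most NK and dendritic cells. The most abundant dendritic members, H2-Ab1, H2-Aa and Cd74, overlapped between the groups. H2-Ab1 had 3991 and 258 CPM in WT_NCD, 877 and 4969 CPM in WT_MCD and 1584 to 2634 CPM in KO_MCD. The comparisons with other cell types below were run on the NK list only. The most abundant NK list member, Fcer1g, is expressed by macrophages too and had 99.3 and 6.91 CPM in WT_NCD, 51.7 and 543 CPM in WT_MCD and 86.3 to 150 CPM in KO_MCD, so its higher WT_MCD mean rests on replicate 2, and 2 of the 21 members, Cd160 and Eomes, stand in other lists. Without WT_MCD replicate 2 the NK list mean change was 2.47, so that library alone does not carry it (camera adjusted p = 0.193 with all libraries and an estimated correlation). The Kupffer change turned to -0.20 without WT_MCD replicate 2 and to -0.33 without WT_NCD replicate 2, so no single library can be named as its carrier. The explanation tested was that a lower share of T cells raises the markers of every other type alike. A rise of only some types was not tested. Hepatocytes were set against NK because they had the smallest p of 6 cell types, and the intervals below do not allow for that choice. Over members of mean 5 CPM or more (5 of hepatocytes) the NK change exceeded the hepatocyte change against WT_NCD by 3.54 in WT_MCD and 4.99 in KO_MCD. The 95% intervals were 1.35 to 5.74 (-0.17 to 6.39 without WT_NCD replicate 1) and 2.98 to 7.0. Adjusted over the 6 types, p was 0.0355 and 0.00698 (t tests on list means). Over members counted in both WT_NCD libraries, a choice made on 1 compared group, the gaps were 3.60 (2.58 to 4.62) and 5.48 (4.54 to 6.41). These values argue only against an equal rise for hepatocyte markers, the type chosen, and do not speak for the other types. The hepatocyte list had already fallen by camera in both comparisons, so a gap was likely beforehand. A lower share of T cells with an unequal rise of other types stays open. Over all members 3 of 8 types in WT_MCD (1 of 5 at 10 CPM) and 4 of 8 in KO_MCD parted from NK after adjustment, but monocytes did not (1.38, -1.46 to 4.23, and 1.40, -1.20 to 4.0), nor did Kupffer cells in WT_MCD (2.12, -0.16 to 4.41), and carry-over of NK cells and an effect of diet on the sorted T cells both stay open.

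Proliferation genes stood lower on the deficient diet, and pan T cell genes stood lower too. The weakest mean change with any 1 library left out was -1.12 for WT_MCD against WT_NCD, so no single library carries it. The proliferation change less the pan T cell change was -0.73 (95% interval -2.49 to 1.03) in WT_MCD and -1.53 (-3.14 to 0.08) in KO_MCD, each against WT_NCD. Without WT_MCD replicate 1 the WT_MCD value was 0.0060 and without replicate 2 it was -1.46, the KO_MCD interval was -2.76 to -0.30 without either one, and the pan T cell call ended without WT_MCD replicate 2 (list mean change -0.18) or WT_NCD replicate 2 (-0.37). Fewer T cells in the sort and less division of T cells therefore cannot be told apart, since with all libraries both intervals hold 0.

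Heat shock genes stood higher in KO_MCD than in WT_MCD, and cell handling after tissue dissociation is a candidate explanation; in KO_MCD against WT_NCD the list was not called (9 of 15 members higher, median log2 fold change 0.03, camera adjusted p = 0.336), and WT_NCD replicate 1 (list mean 0.40) lay within the knockout range (0.19 to 0.67). Within groups heat shock and immediate early means had a Pearson r of 0.70 (exact permutation within groups, p = 0.167, adjusted 0.333) and a Spearman rho of 0.43 (p = 0.583, adjusted 0.583), and r was 0.45 without WT_NCD replicates 1 and 2 (p = 0.333). Handling and genotype cannot be told apart, since these 24 permutations are few and no measure of handling was analysed here. Without WT_MCD replicate 2 the mean change was 0.77 in place of 1.19 and the call ended narrowly (camera adjusted p = 0.0504; 5.41e-08 to 0.689 over its alternatives), so that library may account for part of it. The effect of genotype itself stays open.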
